A study of Mus musculus with 7 samples.

How the data were processed

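The series measured RNA in Langerhans cells, the dendritic cells of the epidermis, of adult wild-type C57:Bl6 mice. Per the labels' protocols, the cells were sorted by flow cytometry into Trizol, pooled to over 10000 cells per sample and passed to the ImmGen consortium, where total RNA was labelled with biotin and hybridised. The 7 samples fall into 4 control samples from naive mice and 3 samples from mice given 12 Gy of radiation. The time between irradiation and sorting and the sex of the mice are not stated in the labels. The labels of control replicates 1 and 4 cite an earlier record each, and those of the other 5 samples cite none. Nothing in the labels says that the samples of a group came from separate mice or pools, so the p-values measure the spread between these samples, which may be technical.

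The deposited values are intensities, 1 per probe set and array, that the authors made by robust multi-array averaging (RMA), per the submitters' processing notes, which name RMA without a version. The array design, the genome build behind its annotation and which arrays were normalised together are not given in the sources used here. The lowest value of an array lay between 3.99 and 4.44 and the highest between 13294 and 19977, so they are on a linear scale and not the log2 scale on which RMA is often given. Both deposited tables hold the same intensities: 174454 of 174454 values were equal within 1e-09. The median intensity per array lay between 80.2 and 88.2, and 6976 of 24922 probe sets (28.0%) held an equal value in at least 2 arrays. The number of arrays, 7, limits the precision of every comparison.

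The log2 of each intensity was taken. The 24922 probe sets carry 21755 gene symbols in the deposited annotation. For the 1854 symbols with several probe sets the one with the highest mean was kept. The lowest 40% of symbols by mean over all 7 arrays were left out (below 6.07 log2, an intensity of 67.3), which left 13053 genes. Of the 21755 symbols, 18705 were current symbols in the RefSeq gene table for GRCm38.p6, 2291 were older synonyms there and 759 matched neither. That table was used for names only, and no coordinates are given. A further limit of the annotation is that 25 symbols had turned into calendar dates, so March1, March8 and Sept3, which belong to gene lists, were not found.

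Irradiated and control samples were compared with lmFit and eBayes (trend = TRUE) of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the 13053 genes and a threshold of 0.05. Log2 fold changes are irradiated minus control. Cdkn1a, the gene of the p21 protein in the series title, also had a two-sided exact permutation test over the 35 splits of the 7 arrays into 4 and 3. Before the data were examined, 34 gene lists were fixed, covering the p53 response, DNA repair, cell cycle, cell death, antigen presentation, inflammation, metabolism and markers of other skin and blood cells. Lists with at least 5 tested members (32) were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run as alternatives, and fry asks whether the genes of a list move one way on balance, without comparing them with other genes.

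The genes named were also set by a rule fixed before the data were examined. It takes Cdkn1a, then the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, leaving out unnamed gene models and antigen receptor segments. From each list it takes up to 3 members past the threshold, or else the member with the highest mean level. It always takes Cd207, Epcam, Mki67, Mdm2 and Ccr7. Sex-linked genes, markers of a library that stood apart, and genes named only from the comparison without that library were chosen after their values were seen, as the text says.

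The alternatives fixed before the data were examined were no filter or a filter on the lowest 60%, eBayes without trend or with robust variances, array weights, quantile normalisation, median centring, the other deposited table, the mean of all probe sets, log2 of the value plus 16, the replicate number as a block, the earlier record as a term, the controls of 1 record status only, each array left out in turn, other thresholds, and a test per gene without shared variance. A comparison of controls 2 and 3 with irradiated 2 and 3 was added after the data had been seen. The test was first run on simulated data: over 5 runs with 200 changed genes among 13053, it recovered 43.4% of 2-fold and 81.4% of 4-fold changes, and 4.94% of its calls were false. In the same runs camera found 5 of 5 lists shifted by 0.5 log2 and 0 of 5 lists that were not shifted. The simulated genes varied independently of each other, so these runs do not test whether the preset correlation suits the real lists. The noise of a simulated gene was normal, with the same spread in every array. These runs therefore do not give the share of false calls when a library stands apart, as in the real data. Figures were drawn with matplotlib 3.10.9.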

Results

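Transcript levels were measured on 7 arrays of sorted mouse Langerhans cells (LC), 4 from naive control mice and 3 from mice given 12 Gy of radiation. The series title links p21, the cell cycle inhibitor encoded by Cdkn1a, to the resistance of these cells to radiation. Each array carried 24922 probe sets, and its median intensity lay between 80.2 and 88.2. Pearson correlations across the 13053 tested genes, which are not independent replicates, were 0.858 or higher among 6 of the arrays. The library labelled irradiated replicate 1 stood apart, with correlations of 0.650 to 0.728 with the others. All 4 controls had high levels of Xist, the X-inactivation RNA of female cells (10.9 to 11.7 log2), and all 3 irradiated samples low ones (5.31 to 5.93).

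The level of Cdkn1a was 11.36 ± 0.10 log2 (SD, n = 4) in control and 12.37 ± 0.36 (SD, n = 3) in irradiated LC, a log2 fold change of 1.01 (SE 0.20, 2.02-fold). All 3 irradiated samples lay above all 4 controls. The limma test over all genes did not pass (adjusted p = 0.0540). The exact permutation test of this single gene gave p = 0.0286 (two-sided), the smallest that 35 splits allow. Without the library labelled irradiated replicate 1, the log2 fold change was 1.22 and the adjusted p 0.0101. Among the other alternatives Cdkn1a passed with the lowest 60% left out, without trend, with array weights and with either rescaling. The adjusted p ranged from 0.00132 to 0.529 over all of them.

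Genes activated by the transcription factor p53 were higher as a group in irradiated LC, with a median log2 fold change of 0.21 over 43 tested members (camera adjusted p = 0.000426; adjusted p = 0.491 with an estimated correlation). Of these, 2 rose, 1 fell and 40 did not pass over all genes; adjusted over the list alone, 5 rose and 1 fell. Camera still called the list with each array left out, but its median was 0.097 without control replicate 4 and 0.042 without irradiated replicate 3. Fry did not call it with all arrays (adjusted p = 0.240), and did without irradiated replicate 1 (adjusted p = 0.0202). The median level in the library labelled irradiated replicate 1, 7.26, lay within the 7.13 to 7.27 of the controls. Those of irradiated replicates 2 and 3, 7.46 and 7.51, lay above. Trp53inp1, which promotes p53-dependent cell death, rose by 2.06 log2 (SE 0.32, adjusted p = 0.0283, n = 4 and 3), and the thiamine transporter gene Slc19a2 rose by 1.33 (SE 0.15, adjusted p = 0.0133), each in 3 of 3 irradiated samples. Ccnd1, the gene of cyclin D1, fell by 1.35 log2 (SE 0.19, adjusted p = 0.0203). Mdm2, whose product degrades p53, was at 8.34 ± 0.39 in control and 9.23 ± 1.21 in irradiated LC (log2 fold change 0.89, adjusted p = 0.391). Its irradiated values were 7.84 in the library labelled irradiated replicate 1 and 9.85 and 9.99 in the others. Without that library 9 members rose and 1 fell, among them Mdm2 (1.58, adjusted p = 0.0268) and Ccng1 (1.66, adjusted p = 0.00945).

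**Figure D1:**
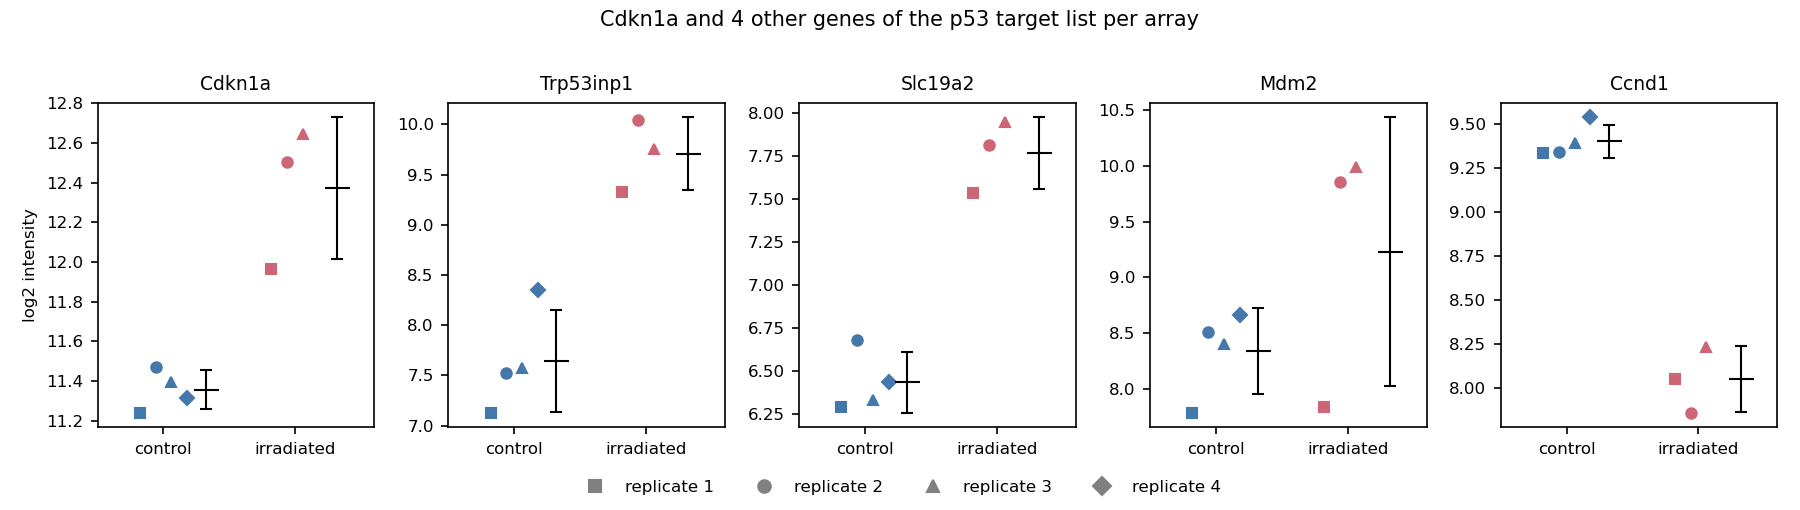
Log2 intensity of Cdkn1a and 4 other genes of the p53 target list in 4 control and 3 irradiated LC samples, with marker shapes for the replicate and black bars for the mean ± SD of each group. Cdkn1a lies between 11.2 and 11.5 in the controls and between 12.0 and 12.6 after irradiation, whereas the Mdm2 values of the groups overlap.

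Over all genes, 15 were higher and 204 lower in irradiated LC (limma, adjusted p under 0.05). Among these 204, leaving out unnamed gene models and antigen receptor segments, the largest falls after Xist were in Ccl17, Sh2d1b1, Pilra and the cyclin gene Ccnb2. The chemokine gene Ccl17 fell by 3.24 log2 (SE 0.55, adjusted p = 0.0355). Sh2d1b1, the gene of an adaptor of SLAM-family receptors, had a log2 fold change of -3.08 (SE 0.21, adjusted p = 0.00333), and the inhibitory receptor gene Pilra one of -3.03 (SE 0.33, adjusted p = 0.01004). The cytokine gene Osm fell by 2.67, the interleukin-2 receptor gene Il2ra by 2.60 and the DNase gene Dnase1l3 by 2.43. The irradiated means of Sh2d1b1 (4.94), Il2ra (5.95) and Dnase1l3 (6.05) lay below the 6.07 log2 used as the limit for dim genes. Those of Ccl17 (6.16) and Pilra (6.17) lay just above this limit. That limit is a filter and not a measured detection limit, so the size of these falls is uncertain. Among the rises after Ddx3y were Lyve1, a hyaluronan receptor gene (2.47, SE 0.40, adjusted p = 0.0298), the small GTPase gene Gem (2.11), the tight junction gene Cldn4 (1.598), Prnp (1.57), the magnesium transporter gene Slc41a1 (1.53), the protease inhibitor gene Serpinb6a (1.39) and Tmem195, now Agmo (1.06). In each of these genes all 3 irradiated samples lay on 1 side of all 4 controls, as the rule for naming them required. In 2446 of 13053 genes (18.7%) the groups did not overlap, where chance gives 5.71%.

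These counts depended on single libraries. Without the library labelled irradiated replicate 1 they were 206 higher and 399 lower, sharing 15 and 197 with the comparison of all 7. Without irradiated replicate 2 they were 0 and 2, and without irradiated replicate 3 they were 7 and 49. Without control replicates 1, 2, 3 or 4 they were 15 and 289, 1 and 19, 2 and 46, and 0 and 2. Against only the controls that cite no earlier record the counts were 0 and 1, with 16 gene lists called. Controls 1 and 4 could not be compared with irradiated samples of their own kind because none cites an earlier record.

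Transcripts of dividing cells were lower after irradiation. All 27 tested genes of G2 and mitosis had lower means, with a median log2 fold change of -1.27 (camera adjusted p = 9.7e-18; adjusted p = 0.444 with an estimated correlation). Of them 11 fell over all genes and 23 adjusted over the list alone. The cyclin genes Ccnb2 and Ccna2, which drive entry into mitosis, fell by 2.92 (SE 0.27, adjusted p = 0.00906) and 2.60 log2 (SE 0.35, adjusted p = 0.0159). Nusap1, a spindle protein gene, fell by 2.11 (adjusted p = 0.0166), to a mean of 5.44 below the limit for dim genes. The irradiated mean of Ccna2, 6.13, lay just above that limit. S phase genes had a median of -0.57 (camera adjusted p = 1.4e-08; adjusted p = 0.444 with an estimated correlation). Of 27 genes 4 fell over all genes and 17 adjusted over the list alone. Among them, the replicative helicase genes Mcm7 and Mcm6 fell by 1.26 and 1.22, to means of 6.14 and 6.21 just above that limit. Rrm2, a ribonucleotide reductase subunit gene, fell by 1.24, to a mean of 5.999 also below the limit for dim genes. Mki67, a marker of cycling cells, was at 9.33 ± 0.41 in control and 8.26 ± 1.06 in irradiated LC and did not pass (log2 fold change -1.08, adjusted p = 0.270; -0.48 without the library labelled irradiated replicate 1).

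Histone genes expressed during DNA replication had a median log2 fold change of -1.36 (35 tested; camera adjusted p = 3.4e-23; adjusted p = 0.444 with an estimated correlation). Of these 19 fell over all genes and 30 adjusted over the list alone. Hist1h2ak fell by 2.33 (SE 0.25, adjusted p = 0.01004), Hist1h2bb by 2.16 and Hist1h2bm by 1.65. Many of these genes are near-identical in sequence, so their probe sets can share signal and single members are uncertain. The direction of all these cell cycle lists was the same without the library labelled irradiated replicate 1, with medians of -1.41 for G2 and mitosis, -0.63 for S phase and -1.34 for histones. Against controls 2 and 3 only the medians were -1.35, -0.60 and -1.39. Genes of DNA damage sensing and double-strand break repair were not called by camera with all arrays (median -0.26, adjusted p = 0.0807) and were called lower by fry (adjusted p = 0.0208), with 0 of 17 past the threshold over all genes and 5 lower adjusted over the list alone. Their medians were 6.54 to 6.61 in the irradiated samples and 6.77 to 7.04 in the controls. Camera called the list without a filter (adjusted p = 2.1e-05) and without irradiated replicate 2 (adjusted p = 0.0324), and the median was -0.13 without the library labelled irradiated replicate 1. With all arrays and an estimated correlation the adjusted p was 0.491. The member with the highest probe signal, Dclre1c, was at 7.99 ± 0.15 and 7.57 ± 1.23.

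**Figure D2:**
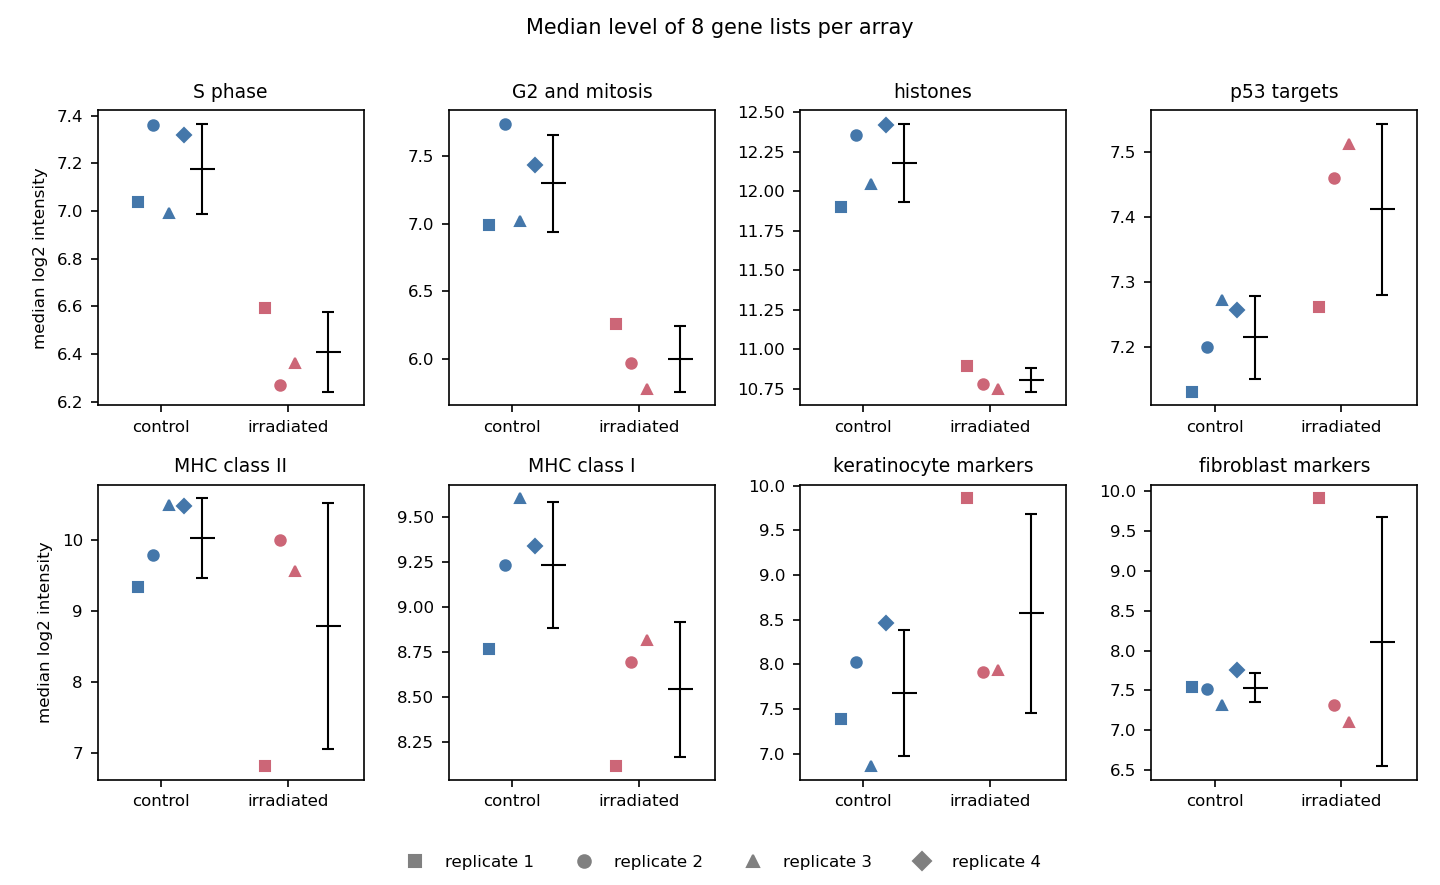
Median log2 intensity of the tested members of 8 gene lists in each of 4 control and 3 irradiated LC samples, with marker shapes for the replicate and black bars for the mean ± SD of each group. The G2 and mitosis medians lie between 5.77 and 6.26 after irradiation and between 6.99 and 7.74 in the controls, and the square of irradiated replicate 1 stands apart in the panels of MHC class II (6.82) and fibroblast markers (9.91).

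Cd207, the gene of langerin that marks LC, was at 12.4 and 11.9 log2 in irradiated replicates 2 and 3 and at 5.64 in the library labelled irradiated replicate 1, against 11.5, 11.0, 8.85 and 8.91 in the controls (adjusted p = 0.976). That library also had low levels of H2-Aa (6.52, where the controls averaged 13.05), Cd74 (7.61 against 13.32) and the leukocyte gene Ptprc (5.61 against 9.87), and a high level of the collagen gene Col1a1 (10.61 against 8.18). H2-Aa, Ptprc and Col1a1 were chosen after their values were seen. The list of LC identity genes was not called (median -0.61, adjusted p = 0.145, 0 of 38 past the threshold). Its median was -0.19 without that library (adjusted p = 0.869). It was called without irradiated replicate 2 (-0.87, adjusted p = 0.0103) or 3 (-0.90, adjusted p = 0.0460), with median centring (-0.48, adjusted p = 0.0278) and without a filter (-0.60, adjusted p = 0.00214). With all arrays and an estimated correlation its adjusted p was 0.814. Its member with the highest probe signal, Mfge8, was at 12.19 ± 0.83 and 11.86 ± 2.16, and Epcam, an adhesion molecule of LC, was at 9.33 ± 0.51 and 8.33 ± 0.85 (adjusted p = 0.264). Without that library the log2 fold change of Epcam was -0.51.

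Genes of MHC class II presentation were lower with all 7 arrays (median -1.28, camera adjusted p = 0.0346; adjusted p = 0.713 with an estimated correlation), but 0 of 15 passed. The list was not called without the library labelled irradiated replicate 1 (median -0.16), nor without control replicate 1 (median -1.52, adjusted p = 0.0959). MHC class I genes were lower with all 7 arrays (median -0.62, camera adjusted p = 9.5e-05, adjusted p = 0.491 with an estimated correlation). They were also lower without the library labelled irradiated replicate 1 (median -0.33). Of 19 members, 1 fell over all genes and 6 adjusted over the list alone. Psmb8, an immunoproteasome subunit gene, fell by 1.43 (SE 0.18, adjusted p = 0.0154). Dendritic cell maturation genes were not called with all arrays (adjusted p = 0.367; adjusted p = 0.887 with an estimated correlation), but were without irradiated replicate 2 (-0.75, adjusted p = 0.0317) and without a filter (-0.51, adjusted p = 0.00965). Of their 34 tested members 1, Ccl17, passed over all genes, and 1 higher and 1 lower adjusted over the list alone. The migration receptor gene Ccr7 was at 10.72 ± 0.24 in control and 8.83 ± 1.75 in irradiated LC (log2 fold change -1.89, adjusted p = 0.205). Without the library labelled irradiated replicate 1, where it was at 6.86, the log2 fold change was -0.91. Lgals9 of the tolerance list fell by 1.52 (SE 0.27, adjusted p = 0.0402), 1 of 24 members past the threshold in a list that was not called (adjusted p = 0.607).

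Keratinocyte markers were higher (median 1.03, camera adjusted p = 2.9e-05; adjusted p = 0.491 with an estimated correlation) with 0 of 21 past the threshold. Krt10 was at 10.02 ± 1.01 and 10.87 ± 1.36, and its log2 fold change without irradiated replicate 1 was 0.064. The keratinocyte median was 9.86 in the library labelled irradiated replicate 1, 7.92 and 7.94 in the other irradiated samples and 6.86 to 8.46 in the controls. Without that library the list was still called, with a median log2 fold change of 0.37 (adjusted p = 0.0349), and the median was 0.65 without control replicate 3. Fibroblast markers (median 0.51, adjusted p = 0.0193; adjusted p = 0.713 with an estimated correlation) and endothelial markers (0.31, adjusted p = 0.0186; adjusted p = 0.491 with an estimated correlation) were higher with all arrays and not called without that library, where their medians were -0.25 and 0.07. The fibroblast list was also not called without control replicate 1 (median 0.49, adjusted p = 0.0967) or without a filter (adjusted p = 0.140). Vim, of the fibroblast list, was at 13.36 ± 0.07 and 13.19 ± 0.32, and Egfl7, of the endothelial list, at 6.97 ± 0.21 and 7.28 ± 0.13. T cell markers were called higher (median 0.18, adjusted p = 0.0108; adjusted p = 0.491 with an estimated correlation) with 0 of 13 past the threshold over all genes and 2 higher and 1 lower adjusted over the list alone. The T cell median was 7.63 in irradiated replicate 3, while 6.34 and 6.48 in replicates 1 and 2 lay within the 6.22 to 6.48 of the controls. The median log2 fold change was 0.51 without irradiated replicate 1 and 0.26 without replicate 3, and the list stayed called (adjusted p = 0.00235 and 0.0460). The member with the highest probe signal, Cd7, was at 8.20 ± 0.72 and 8.16 ± 1.16. Dermal dendritic cell markers were lower (median -0.94, adjusted p = 0.0102; adjusted p = 0.491 with an estimated correlation), with Wdfy4 as the 1 of 11 that fell (-1.29, SE 0.23, adjusted p = 0.0396), and their median was -0.77 without that library (adjusted p = 0.0522), with all 11 members negative.

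Markers of monocytes and macrophages, melanocytes, mast cells, and erythroid cells and platelets were not called (adjusted p = 0.557, 0.145, 0.665 and 0.0678). The erythroid and platelet median of 0.98 was -0.19 without irradiated replicate 1 and 1.81 without replicate 3, where the list was called (adjusted p = 0.00574; adjusted p = 0.491 with all arrays and an estimated correlation). The neutrophil and B cell lists, with 4 and 3 tested members, were too small to test. Their members with the highest probe signal did not pass: Lyz2 (11.28 ± 1.97 and 10.90 ± 1.90), Gpnmb (8.06 ± 0.60 and 8.24 ± 0.51), Cpa3 (7.62 ± 0.89 and 7.12 ± 1.25), Hba-a1 (8.44 ± 0.83 and 9.90 ± 3.31), Csf3r (7.60 ± 0.70 and 6.52 ± 0.16) and Cd79b (7.25 ± 0.56 and 6.79 ± 0.23), given as control and irradiated log2 means ± SD.

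Oxidative phosphorylation genes had a median log2 fold change of -0.57 (camera adjusted p = 1.2e-06; adjusted p = 0.491 with an estimated correlation), and 2 of 37 fell over all genes and 16 adjusted over the list alone. The complex II gene Sdhb fell by 1.05 (SE 0.19, adjusted p = 0.0396) and the complex I gene Ndufb7 by 0.80. Cholesterol synthesis genes had a median of -0.51 (adjusted p = 0.000326; adjusted p = 0.491 with an estimated correlation), and 1 of 24, Nsdhl, fell (-1.09, adjusted p = 0.0376), with 6 lower adjusted over the list alone. Of 24 genes of the Nrf2 list, which was called without control replicate 1 (adjusted p = 0.0340), with median centring (0.0445) and without a filter (0.00406) but not with all arrays (0.0929; 0.698 with an estimated correlation), the pentose phosphate pathway genes G6pdx and Tkt fell by 1.36 and 1.25 (adjusted p = 0.0268 for both).

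Genes induced by type I interferon (median -0.47, adjusted p = 0.0193; adjusted p = 0.814 with an estimated correlation; 0 of 34 past the threshold) and lysosomal genes (median -0.81, adjusted p = 0.0394; adjusted p = 0.814 with an estimated correlation; 0 of 28) were lower with all arrays and not called without the library labelled irradiated replicate 1, where their medians were -0.34 and -0.31. They were also not called without control replicate 3 (medians -0.28 and -0.65) or 4 (-0.36 and -0.70). Without control replicate 1 the medians were larger (-0.89, adjusted p = 6.9e-06, and -0.98, adjusted p = 0.000792), as they were against controls 2 and 3 only (-0.90 and -0.91). Cxcl10 was at 11.10 ± 0.76 and 11.18 ± 0.49, and Psap at 11.73 ± 0.93 and 10.68 ± 0.18. Pro-apoptotic genes were lower (median -0.33, adjusted p = 0.0108; adjusted p = 0.491 with an estimated correlation), with 0 of 20 past the threshold over all genes and 6 lower adjusted over the list alone. Cycs, whose probe sets differ in sign, was at 10.47 ± 0.19 and 10.30 ± 0.33. Anti-apoptotic genes were not called (median 0.04, adjusted p = 0.762), and Mcl1 was at 10.28 ± 0.21 and 10.35 ± 1.32. Without that library the anti-apoptotic list was higher (median 0.35, adjusted p = 0.00442; adjusted p = 0.379 with an estimated correlation).

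Immediate-early and heat-shock genes were higher (median 0.13, adjusted p = 0.0156; adjusted p = 0.491 with an estimated correlation), with 0 of 30 past the threshold over all genes and 1 higher adjusted over the list alone. This call depended on single libraries and on the filter. The median was 0.35 without irradiated replicate 1 (adjusted p = 7.7e-06), 0.041 without replicate 2 (adjusted p = 0.0763) and 0.026 without replicate 3 (adjusted p = 0.144), and the list was not called without a filter (adjusted p = 0.221). Hspa8 was at 12.87 ± 0.23 and 12.68 ± 0.47. Inflammatory cytokines, the unfolded protein response and senescence-associated secreted factors were not called (adjusted p = 0.762, 0.985 and 0.762). Ccl3 (12.32 ± 0.78 and 12.11 ± 1.52), Hspa5 (11.28 ± 0.38 and 11.37 ± 1.00) and Plau (10.34 ± 0.34 and 9.84 ± 0.56) did not pass. Cytosolic ribosomal protein genes were not called (median -0.05, adjusted p = 0.698), and their median was 0.06 after quantile normalisation and 0.08 after median centring. Rps6, whose probe sets differ in sign, was at 13.26 ± 0.11 and 13.28 ± 0.06. Housekeeping reference genes were lower (median -0.45, adjusted p = 0.00995; adjusted p = 0.491 with an estimated correlation). Gapdh fell by 0.65 (SE 0.10, adjusted p = 0.0284) with all arrays and was at -0.53 (adjusted p = 0.0583) after median centring. Without the library labelled irradiated replicate 1 the housekeeping median was -0.33, which camera did not call (adjusted p = 0.0548) and fry did (adjusted p = 0.0495). Median centring moved the median log2 fold change of all genes by 0.12, from -0.05 to 0.07. Relative to these medians Cdkn1a was at 1.06 and Gapdh at -0.60 before and after centring. Centring shifts all genes of an array alike, so these relative values could not change and do not test the scaling.

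With a preset correlation, 18 of the 32 tested lists were called, 6 higher and 12 lower. Without the library labelled irradiated replicate 1, 12 were called, of which 11 were also called with it. With an estimated correlation 0 were called. Fry called 6, of which 5 were among the 18 and 1, the DNA damage list, was not. The inflammatory, unfolded protein response and ribosomal lists had medians below 0 and a camera direction above it, and the medians and means of the anti-apoptotic, senescence, mast cell, neutrophil and B cell lists differed in sign.

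Xist and 4 Y-linked genes separated the groups completely. Xist was at 11.41 ± 0.37 log2 in the 4 control and 5.57 ± 0.32 in the 3 irradiated samples (log2 fold change -5.83, SE 0.28, adjusted p = 0.000468). Its irradiated values lay below the 6.07 log2 used as the limit for dim genes, so the size of the fall is uncertain. The same holds for the rises of the Y-linked genes from their control levels. Ddx3y, on the Y chromosome, was at 4.70 ± 0.50 and 7.996 ± 1.15 (log2 fold change 3.30, SE 0.51, adjusted p = 0.0268). The Y-linked genes Eif2s3y, Uty and Kdm5d, chosen after the data had been seen and too dim for the filter, were higher in all 3 irradiated samples by 3.37, 2.499 and 1.03 log2 (adjusted p = 0.0168, 0.0168 and 0.0267 without the filter). The labels give no sex, so every difference above is also a difference between samples with high and with low Xist.

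**Figure D3:**
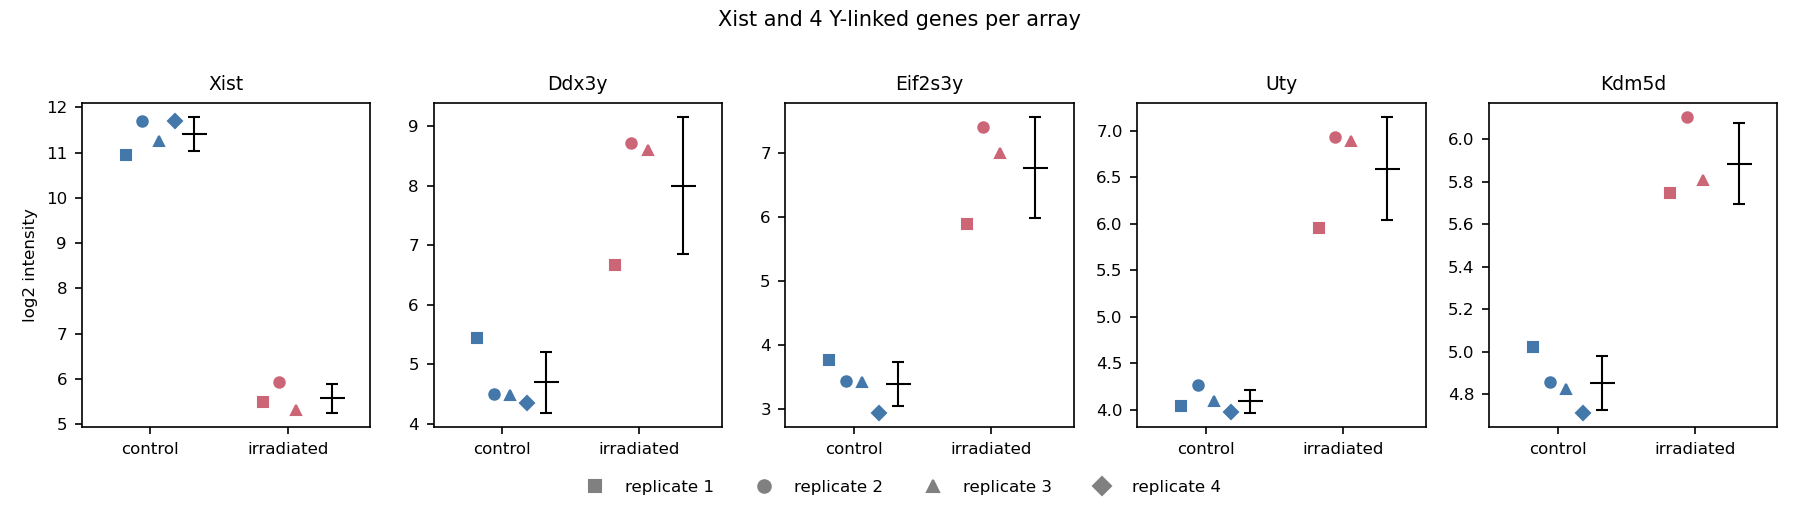
Log2 intensity of Xist and 4 Y-linked genes in 4 control and 3 irradiated LC samples, with marker shapes for the replicate and black bars for the mean ± SD of each group. Xist lies between 10.9 and 11.7 in the controls and between 5.31 and 5.93 after irradiation, and each Y-linked gene is higher in every irradiated sample than in every control.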

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

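The tests in this part were chosen after the result was seen, except the splits of the samples, the comparison with controls 2 and 3 and the test of the signal range. Of 98 results looked at in the 4 controls, 3 had 1 sample far from the others, where chance gives about 4.9. Dclre1c was at 8.21 log2 in control replicate 3 and at 7.88 to 7.94 in the others. Ddx3y was at 5.45 in control replicate 1 and at 4.35 to 4.51 in the others. The median of the melanocyte list was 7.10 in control replicate 1 and 6.84 to 6.87 in the others.

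The number of genes called between irradiated and control LC was set against other splits of the 7 arrays. The real split called 219 genes and the highest of the other splits called 0. Only the real split, 1 of 35, reached that number, a share under the threshold of 0.05 and the smallest these splits allow. Each other split mixes control and irradiated arrays, so any difference between the groups, the sex-linked one included, could give this result. The splits argue against an arbitrary grouping of the arrays and do not tell the cause of the difference. The lower cell cycle and histone genes were weighed further. The other cells in the library labelled irradiated replicate 1 are argued against as the cause by the G2 and mitosis median of -1.41 without that library, and the controls that cite an earlier record by a median of -1.35 against the remaining controls. A different sex of the mice stays open and cannot be told apart from irradiation, since 0 arrays had an Xist level within the range of the other group. Irradiation, the difference that the design names, stays open with it.

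High Xist in the controls and Y-linked transcripts after irradiation could come from female control and male irradiated mice, and 4 of 4 Y-linked genes were higher in every irradiated sample than in every control, as this needs. Of 4 X-linked genes that escape inactivation, which this explanation would have lower after irradiation, Kdm6a (-0.90) and Eif2s3x (-0.69) were lower in every irradiated sample, while Kdm5c (-0.20) did not separate the groups and Ddx3x was at 0.63. None of these 4 passed with all 7 arrays. A loss of Xist RNA in irradiated female cells is argued against by the Y-linked genes, whose median log2 fold change was 2.90.

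The low MHC class II and LC transcripts of the library labelled irradiated replicate 1 may reflect other cells, keratinocytes and fibroblasts among them, in place of LC, although cells were sorted. Its fibroblast median lay 2.49 log2 above the mean of the other 6 arrays, with Col1a1 at 10.61 and Krt14 at 11.65 (7.69 to 11.38 in the controls). Its erythroid and platelet, endothelial, mast cell and B cell medians lay 2.46, 1.20, 0.94 and 0.66 above that mean and above every other array, while its T cell median lay at -0.25 and its monocyte and macrophage median at -1.66. The test of a compressed signal range was its ribosomal protein median, at -0.27 relative to the other arrays, against -3.13 for MHC class II. That gap argues against compression as the whole cause. A narrower range stays open. Its ribosomal median of 10.18 lay below every other array (10.26 to 10.69). The intensity exceeded only by its brightest probe sets was 604, against 754 to 915 in the others. Its median intensity of 88.2 was the highest, although its maximum of 19617 lay within the range of the others (13294 to 19977). Irradiation of LC alone is argued against by the other irradiated samples, the lower of which had an MHC class II median 0.23 above the lowest control.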

How the results depend on the processing

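The comparison of controls 2 and 3 with irradiated 2 and 3 was added after the data had been seen, and all other alternatives were planned. The counts of 15 genes higher and 204 lower stayed within 1.5 times with the lowest 60% left out (14 and 220), without trend (20 and 292), with robust variances (15 and 200), with quantile normalisation (21 and 138), with the mean of all probe sets (16 and 192) and with 16 added before the log2 (15 and 203). The other deposited table holds the same values, so it tests nothing. Without a filter the counts were 13 and 130, with array weights 831 and 2645, and with median centring 17 and 117. They were 0 and 1 with the earlier record as a term, with controls 2 and 3 only and with controls 1 and 4 only, and 1 and 0 in the added comparison. These settings use fewer samples or residual degrees of freedom. Leaving out 1 array in turn gave 0 to 206 genes higher and 2 to 399 lower, the highest without irradiated replicate 1. At adjusted p under 0.01 the counts were 0 and 18, under 0.10 they were 46 and 593, with a 2-fold minimum 10 and 145, and in the test per gene without shared variance 0 and 15. Same-numbered samples did not deviate together (r = 0.021, -0.055 and 0.168), and with the replicate block, a pairing that the labels do not state, 0 genes were higher and 0 lower and 17 lists were called. Cdkn1a kept its direction in every alternative and crossed the threshold with the lowest 60% left out and without trend (1.01 in both; adjusted p = 0.0422 and 0.0423), with array weights (1.10), quantile normalisation (1.18), median centring (1.14) and without irradiated replicate 1 (1.22). Leaving out 1 array in turn gave 0.88 to 1.22. The 18 called lists became 11 with the lowest 60% left out, 11 with array weights, and 0 with an estimated correlation. Fry called 6, of which 5 were among the 18. Of 701 list results, 643 kept their side of the threshold, 41 lost a call, 17 gained one and 0 were called in the opposite direction. For lists, unlike for genes, a change of sign alone was not counted as a reversal. Such changes occurred, as in the fibroblast list, whose median was 0.51 with all arrays and -0.25 without irradiated replicate 1. Of 1403 results of named genes, 980 kept their side, 352 lost a call and 10 gained one. The remaining 61, from 15 genes that did not pass with all arrays and passed in none of these alternatives, reversed. The reversed log2 fold changes were Ccl3 0.39, Cd207 1.96, Cd7 0.19, Cxcl10 -0.11, Dclre1c 0.038, Hspa8 0.041, Mfge8 0.60 with array weights, Cd7 0.092 with quantile normalisation, Cd207 0.024, Cd7 0.084 with median centring, Cd207 0.0078 with 16 added, Ccl3 0.030, Cd7 0.071 with the replicate block, Cd207 0.046, Cd7 0.026, Cxcl10 -0.29, Hspa5 -0.043 with controls 2 and 3 only or the earlier record as a term, Lyz2 0.55, Rps6 -0.019 with controls 1 and 4 only, and Ccl3 0.48, Cd207 2.20, Cd7 0.58, Cd74 0.11, Cxcl10 -0.049, Cycs 0.12, Dclre1c 0.20, Hba-a1 -0.37, Hspa8 0.12, Mfge8 0.93 in the added comparison. Leaving out 1 array in turn gave Ccl3 -0.73 to 0.66, Cd207 -1.30 to 2.06, Cd7 -0.64 to 0.51, Cd74 -2.82 to 0.14, Cxcl10 -0.29 to 0.32, Cycs -0.33 to 0.0072, Dclre1c -0.87 to 0.28, Hba-a1 -0.30 to 2.98, Hspa5 -0.26 to 0.67, Hspa8 -0.32 to 0.089, Lyz2 -1.34 to 0.71, Mcl1 -0.34 to 0.83, Mfge8 -1.004 to 0.91, Rps6 -0.014 to 0.072, Vim -0.30 to 0.0062. Apart from the settings with fewer samples, the cause was not tested. Signal over background limits the dimmest genes. The filter left out those dim on average, and kept genes that are dim in 1 group only.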

Other observations

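The genes in this paragraph were chosen after their values were seen, from the comparison without the library labelled irradiated replicate 1, which rests on 4 control and 2 irradiated samples. In that comparison the list of dendritic cell maturation and migration genes was not called (median -0.27, 14 members above 0 and 20 below, adjusted p = 0.284). Of its 34 tested members 5 passed as higher and 1 as lower. Among those 5, the costimulatory genes Cd83 and Cd86 were higher by 1.52 (adjusted p = 0.0104) and 1.17 log2 (adjusted p = 0.0153). The transcription factor gene Relb was higher by 0.97 (adjusted p = 0.0309) and Mreg by 2.04 (adjusted p = 0.0443). Irf4, a transcription factor gene of the LC identity list and not of this one, was higher by 2.01 (adjusted p = 0.0286). Of the 38 tested members of the LC identity list, 1 passed as higher and 1 as lower. The tight junction gene Ocln was at 5.53 to 6.14 in the controls and at 9.09 and 9.58 in irradiated replicates 2 and 3 (3.50, adjusted p = 0.00349). The size of this rise is uncertain, since the control mean of 5.84 lies below the 6.07 used as the limit for dim genes. The chemokine gene Cxcl9, induced by interferon, was at 7.69 to 10.56 in the controls and at 5.86 and 5.77 in irradiated replicates 2 and 3 (a fall of 3.74, adjusted p = 0.0427). Both irradiated values lie below that limit, so the size of this fall is uncertain too. The metalloproteinase gene Mmp12 was lower as well (-2.67, adjusted p = 0.0463). In the library labelled irradiated replicate 1, Cd83 was at 7.86, Cd86 at 5.62 and Ocln at 6.12. With all 7 arrays none of these genes passed.

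The T cell genes named here were also chosen after their values were seen, and none passed with all 7 arrays. The T cell receptor segment Tcrg-V3, used by the dendritic epidermal T cells of mouse skin, was at 4.62 to 5.08 log2 in the controls and at 5.73, 8.29 and 10.01 in irradiated replicates 1, 2 and 3. Cd3e was at 6.17 to 6.67 in the controls and at 6.78, 7.30 and 8.71 in the same samples, and Cd3g at 5.05 to 5.63 and at 5.25, 6.57 and 8.46. Nkg7 followed the same order, at 5.43 to 6.24 in the controls and at 6.24, 6.98 and 8.30. Of the other 4 genes looked at, Cd2 had that order in the irradiated samples (5.79, 5.96 and 6.64). These values did not rise above its 6.25 to 7.19 in the controls (log2 fold change -0.54). Cd3d, Gzmb and Thy1 did not follow the order. Cd3d was at 4.62 to 4.99 in the controls and at 5.17, 4.99 and 5.31. Gzmb was highest in irradiated replicate 1 (5.93), as was Thy1 (9.21, then 7.28 and 7.63). The controls also differed among themselves: the median of the monocyte and macrophage list ran from 6.37 to 10.32, that of the interferon list from 6.78 to 8.71, and Cd207 from 8.85 to 11.49. Between the controls that cite an earlier record and those that cite none, limma called 0 genes, with 34 of 13053 at an unadjusted p under 0.05. That is fewer than chance would give. With 2 arrays on each side the comparison has little power, so it does not show that these controls are alike.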
